A study of Homo sapiens with 10 samples.

How the data were processed

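Libraries were made from monocytes of 10 donors, 5 with chronic periodontitis and 5 healthy controls, each library being 1 donor. Per the labels' protocols, monocytes were isolated from whole blood by negative selection, total RNA was extracted with a column kit, and libraries were made with poly(A) selection. Groups were taken from the disease label of each sample. Replicate numbers follow the order of the records only and pair no samples. No batch, date or other covariate entered a test.

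The authors deposited 1 gene table per library holding FPKM, the lower and upper bound of the FPKM confidence interval and a status, per the file headers, with 25593 rows in the same order in every file. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2 and DESeq were used by the submitters; the role of each, the genome build and the annotation are not given in the sources used here. FPKM are normalized values, so a count model was not used and all tests ran on a log2 scale. Rows of the Y chromosome, XIST and TSIX (138 rows) were left out throughout. 97 genes had an estimate marked as failed in at least 1 library; their FPKM were kept, 91 of them being tested, and leaving them out was an alternative. RPL11 and PKM2 are among them. Zeros in the tables occur for small nuclear and nucleolar RNAs that every cell uses. The rule below had left small RNA genes unnamed before the data were examined. Coordinates are those of the tables with the start shifted by 1, because lengths matched GRCh38.p14 gene lengths for 3565 of 19856 genes if the start counts from 0 and for 187 if it counts from 1. Only 59 end coordinates equal those of GRCh38.p14, so the tables use another build, and no coordinate was converted.

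Depth was estimated from the deposited intervals. The distance from the FPKM to the upper bound was taken as 2 Poisson standard deviations, which implies a fragment number for each value; of values between 0.5 and 60 fragments, 59.3% came out whole within 0.01 (56.4% to 60.5% per library). Relative depth was the median over genes with whole numbers in both libraries of fragments per FPKM against control 1, and totals are approximate. At a given FPKM the deeper libraries hold proportionally more fragments and less counting error; p-values below carry no separate counting interval.

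FPKM were divided by median-of-ratios factors over genes above 0 in every library. Genes with a mean scaled FPKM of 1 or more, 12107 in all, were tested on log2(scaled FPKM + 1) with limma 3.58.1 (lmFit, eBayes with trend, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference is on that scale, which understates the change of low genes. The median difference over all tested genes was 0.03 after scaling and -0.16 for FPKM as deposited, so all differences are relative to the bulk of genes. Of 33 gene lists, 31 had 5 or more tested members; they were tested with limma camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A list score is the mean of log2(scaled FPKM + 1) over tested members, compared by a two-sided exact permutation test. The separation of groups was tested over all 126 splits of the libraries. Lists overlap in a few genes, and CD36, CCL5 and the integrin genes ITGB1 and ITGA5 of the migration list are also expressed by platelets. Correlations over the 10 libraries used 100000 permutations. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.

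Before the data were examined, the tests, lists, naming rule and most alternatives were fixed. The rule named 12 genes per direction by size among those past the adjusted threshold and, where fewer passed, filled up with the smallest unadjusted p among genes with a mean scaled FPKM of 5 or more in either group; since none passed, all were filled. It added up to 4 tested members of each list by smallest p; after a first run over the alternatives had been seen, this was lowered to 2 for lists that did not pass, which also lowered the number of values to report. Small RNAs, clone names and genes with common deletion or haplotype differences were not named. The result of 1 further gene is not reported here. Fixed with them were other pseudocounts (0.1 and 0.01), no filter and a filter at 5, FPKM as deposited, quantile normalization, leaving out each library in turn, limma with robust eBayes, with arrayWeights and without trend, exact permutation per gene, other list tests and scores, and the most variable genes alone. Alternatives added after seeing the data were leaving out failed estimates, limma voom on implied fragments, depth or platelet score as a covariate, removal of length and GC trends, leaving out the 3 shallowest libraries, and thinning to the shallowest depth. Length and GC came from GENCODE v29 transcripts matched by symbol or synonym, for 91.3% of tested genes.

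The tests were tested on simulated data: 20 sets of 12107 genes with the means and spreads of this comparison, 200 genes changed in each. Of genes changed by 1 log2 unit 37.1% were called, of those changed by 2 units 84.5%, and 4.96% of calls were unchanged genes. A list shifted by 0.5 was called by camera in 100% of sets, with 0.1 unshifted lists called per set. The simulated genes vary independently, which real genes do not. Isoform-level values and replication in other cohorts were not analysed here.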

Results

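RNA sequencing was used to measure gene expression in monocytes from the peripheral blood of 5 donors with chronic periodontitis, an inflammatory disease of the tissues that hold the teeth, and of 5 healthy controls. Monocytes are circulating phagocytes that can become macrophages or osteoclasts. They had been isolated from blood by removal of other cells, so the product can hold some platelets and other blood cells. Each donor gave 1 library, of messages selected by their poly(A) tail. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the size of the library), and the depth implied by their confidence intervals ran from 3.98 to 16.4 M fragments per library. Mean depth was 8.77 ± 5.06 M fragments in the periodontitis libraries and 11.8 ± 2.31 M fragments in the controls (SD, n = 5 each), and log2 depth differed with a two-sided exact permutation p of 0.190. The periodontitis libraries 2, 3 and 4 were the shallowest, at 7.24, 5.06 and 3.98 M fragments, and periodontitis 1 was the deepest.

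The comparison asked which genes and gene groups differ in monocytes between chronic periodontitis and health. In periodontitis, messages for the protein-making machinery, for mitochondrial respiration, for antigen presentation and for chaperones fell relative to other genes, and platelet messages rose. These shifts were smaller without the 3 shallowest libraries, all from periodontitis: the medians were then -0.24 (ribosomal), -0.22 (oxidative phosphorylation), -0.09 (MHC class II), -0.26 (heat shock) and 0.31 (platelet, limma camera adjusted p = 0.314, not passing). With all libraries the ribosomal protein list, which encodes components of both ribosomal subunits, fell by a median of 0.79 on the log2 scale, with all 49 of its measured members lower. The platelet list had a median difference of 1.24, with all 20 measured members higher. Of 100 splits of the libraries, the real one included, 57 gave as many lists passing limma camera as the real 7. Chance could therefore not be excluded for these lists. With the correlation between genes estimated from the data, 0 of the 31 lists passed (smallest p = 0.0673, adjusted 0.830), and no single gene passed an adjusted p of 0.05. All statements on single genes below therefore give values only.

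For the ribosomal proteins the list score, the mean of log2(scaled FPKM + 1) over members, was 8.81 ± 0.70 against 9.62 ± 0.38 in controls (SD, n = 5 each). The list passed limma camera with an adjusted p of 1.43e-15; with an estimated correlation p = 0.148. RPS24 stood at 1455 ± 579.9 against 2787 ± 529.8 FPKM, RPL27 at 1008 ± 634 against 2172 ± 497 and RPL8 at 1156 ± 494 against 1959 ± 228 (periodontitis against control, mean ± SD, n = 5 each). Nuclear-encoded oxidative phosphorylation genes fell by a median of 0.52 on the log2 scale, with 29 of 32 members lower and a limma camera adjusted p of 7.86e-08; with an estimated correlation p = 0.0879. With log2 depth as a covariate the ribosomal median was -0.44 and the oxidative phosphorylation median -0.30. Both lists passed limma camera there and without the 3 shallowest libraries (largest adjusted p = 6.72e-05). These calls used the preset inter-gene correlation, which lies below the 0.83 (ribosomal) and 0.35 (oxidative phosphorylation) estimated from all libraries. As scores without the 3 shallowest libraries, 0 lists passed the exact permutation test (smallest adjusted p = 0.934). Few periodontitis libraries were left there, so that 0 was nearly fixed by the size of the groups and decides nothing. Whether either fall is independent of depth was therefore not settled. Among the oxidative phosphorylation genes, UQCRC1 and UQCRFS1, subunits of respiratory complex III, had log2 differences of -0.94 ± 0.27 and -1.02 ± 0.31 (SE). COX5A and COX5B, subunits of cytochrome c oxidase, had differences of -1.14 ± 0.37 and -0.59 ± 0.19.

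Genes of MHC class II antigen presentation fell by a median of 0.69 on the log2 scale, 16 of 19 members being lower (limma camera adjusted p = 2.28e-04; with an estimated correlation p = 0.0762). Their median was -0.09 without the 3 shallowest libraries and -0.39 with log2 depth as a covariate (limma camera adjusted p = 0.0353 and 0.00130), and the list did not pass with the platelet score as a covariate (-0.35, adjusted p = 0.0991). CD74, the invariant chain that escorts class II molecules, averaged 2973 ± 801 against 5324 ± 398 FPKM, and HLA-DMA, which loads peptide onto them, averaged 182 ± 47.2 against 281 ± 48.7 (periodontitis against control). HLA-DRB1 and HLA-DPA1 had log2 differences of -1.10 ± 0.36 and -1.05 ± 0.38 (SE), with the caution that reads of HLA-DRB1 can be shared with its near-identical relatives. Heat shock proteins fell by a median of 0.58, with 14 of 17 members lower (adjusted p = 2.72e-04 by limma camera; with an estimated correlation p = 0.0673), the median being -0.26 without the 3 shallowest libraries and -0.40 with log2 depth as a covariate. The examples were chaperones of the cytosol and of the endoplasmic reticulum: HSP90AB1 at -0.96 ± 0.33, DNAJA1 at -0.99 ± 0.32, HSPA5 at -0.99 ± 0.34 and HSP90B1 at -0.70 ± 0.23.

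Classical monocyte markers fell by a median of 0.74 on the log2 scale, 16 of 20 being lower (limma camera adjusted p = 0.0114; with an estimated correlation p = 0.307). CD14, the co-receptor for bacterial lipopolysaccharide, averaged 283 ± 153 against 505 ± 125 FPKM. FCN1, a secreted lectin, had a log2 difference of -0.75 ± 0.30 (SE), and CD36, a scavenger receptor that platelets also carry, one of 0.53 ± 0.24. Without the 3 shallowest libraries the list's median was 0.14 with an adjusted p of 0.403, and with log2 depth as a covariate -0.14 (adjusted p = 0.734). Its call was also lost without periodontitis replicate 3 (median -0.41, adjusted p = 0.0717) and without periodontitis replicate 4 (-0.60, adjusted p = 0.0646). With the platelet score as a covariate its median was -0.16 (limma camera adjusted p = 0.901). Non-classical monocyte markers did not pass, with 12 of 20 higher (adjusted p = 0.639); VMO1 averaged 20.2 ± 12.6 against 7.60 ± 6.09 FPKM and the complement gene C1QA 11.1 ± 2.33 against 38.7 ± 42.0, the control mean being 20.2 without control 2.

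Platelet markers rose in periodontitis (limma camera adjusted p = 8.91e-07; with an estimated correlation p = 0.209), the list score being 9.93 ± 1.20 against 8.75 ± 0.74 in controls. ITGA2B, the platelet integrin chain, averaged 1207 ± 747 against 374 ± 255 FPKM, and GP9 and GP1BA, parts of the von Willebrand factor receptor, averaged 746 ± 386 against 259.9 ± 155 and 154 ± 85.1 against 62.9 ± 30.2. Platelet messages were thus abundant in both groups. The median was 0.31 without the 3 shallowest libraries, and the list then did not pass (adjusted p = 0.314); with log2 depth as a covariate it was 0.49 (adjusted p = 0.00371). Basophil and eosinophil markers rose by a median of 1.08, 6 of 7 members being higher (adjusted p = 0.0341 by limma camera; with an estimated correlation p = 0.147). HDC, the histamine-forming enzyme, averaged 2.19 ± 2.36 against 0.296 ± 0.166 FPKM and PRG2, a granule protein, 5.39 ± 5.17 against 1.57 ± 1.06; without periodontitis 4 their periodontitis means were 1.14 and 3.29. The list lost its call without periodontitis replicate 1 (1.17, adjusted p = 0.150), without control replicate 2 (1.12, adjusted p = 0.0506) and without periodontitis replicate 4 (0.50, adjusted p = 0.331). The call was lost as well with depth as a covariate (0.64, adjusted p = 0.0692), after thinning to the shallowest depth (0.95, adjusted p = 0.0752), without the 3 shallowest libraries (0.48, adjusted p = 0.0872) and with limma arrayWeights (0.74, adjusted p = 0.166). With the platelet score as a covariate the list did not pass either (0.62, limma camera adjusted p = 0.221). Its size depended on the treatment of low values, the median being 1.79 and 2.02 at pseudocounts of 0.1 and 0.01, 1.85 by limma voom and 0.48 with no filter.

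None of the lists for other blood cells passed on scaled FPKM with all 10 libraries and no covariate; the calls of other settings stand at the end of this paragraph. Erythroid genes had 7 of 11 members higher (limma camera adjusted p = 0.154), and the globin gene HBB averaged 325 ± 677 against 17.2 ± 20.1 FPKM, the periodontitis mean being 22.4 without periodontitis 4 and the control mean 9.95 without control 1. B and plasma cell markers had 6 of 7 higher (adjusted p = 0.139), with BANK1 at 15.5 ± 4.52 against 8.37 ± 3.76 FPKM. Neutrophil markers had 11 of 18 higher (adjusted p = 0.350), NK cell markers 8 of 13 (adjusted p = 0.540) and dendritic cell markers 2 of 13 (adjusted p = 0.0987), all by limma camera. CMTM2, a neutrophil gene, averaged 18.9 ± 16.4 against 5.64 ± 1.28 FPKM, GNLY, a cytotoxic granule gene, 43.5 ± 17.9 against 26.9 ± 26.1, and CLEC10A, a dendritic cell lectin, 16.2 ± 8.49 against 23.1 ± 3.55. The periodontitis mean of CMTM2 rested largely on periodontitis 4, and the control mean of GNLY was 15.7 FPKM without control 4. T cell markers had 4 members above the filter and were not tested; the 17 markers in the tables summed to 11.8 ± 3.05 FPKM against 12.4 ± 11.1 in controls (SD, n = 5 each). Control 1, at 31.8, set that mean, and the other 4 controls averaged 7.51 ± 2.95 FPKM, below periodontitis. NK cell markers passed limma camera as higher with depth as a covariate (median 0.36, adjusted p = 0.0428), with the platelet score as a covariate (0.76, adjusted p = 9.84e-05) and without the 3 shallowest libraries (0.44, adjusted p = 0.0332). Neutrophil markers passed as higher without the 3 shallowest libraries (adjusted p = 0.0143) and without control replicate 4 (0.0254). B and plasma cell markers passed with FPKM as deposited (adjusted p = 0.0399) and without control replicate 1 (0.0197), and erythroid markers with FPKM as deposited (0.0399) and without periodontitis replicate 5 (0.0459). Dendritic cell markers passed as lower without control replicate 2 (median -0.48, adjusted p = 0.0300). With an estimated correlation, all libraries in, p was 0.695 for the NK, 0.468 for the neutrophil, 0.358 for the B and plasma cell, 0.258 for the erythroid and 0.259 for the dendritic cell list.

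**Figure D1:**
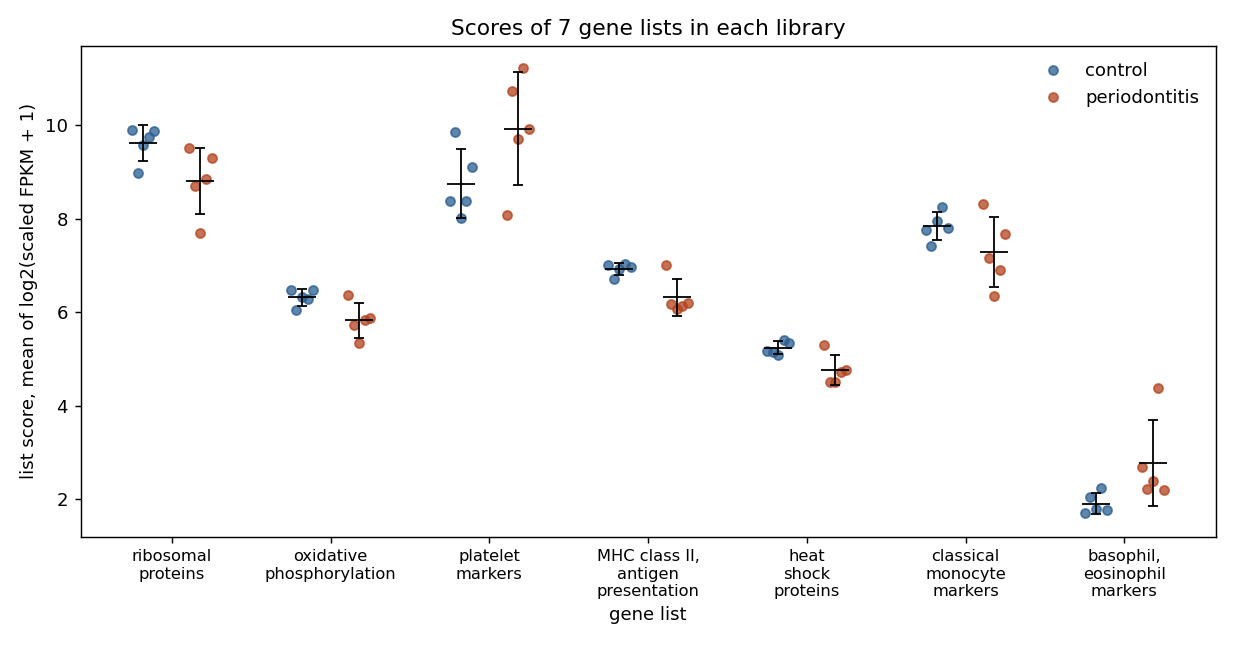
Score of each of the 7 gene lists that passed limma camera, on the vertical axis in log2(scaled FPKM + 1), for each control and periodontitis library; points are libraries, horizontal bars are group means and error bars are SD (n = 5 each). The ribosomal protein mean was 8.81 in periodontitis and 9.62 in controls, the platelet mean was 9.93 and 8.75, and points of both groups overlap in every list.

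The lists of inflammation did not pass limma camera. Inflammatory cytokines and chemokines had 14 of 20 members lower (adjusted p = 0.540), with CCL5, a chemokine that platelets also store, at 3600.1 ± 3628 against 942 ± 445 FPKM and the monocyte attractant CCL2 at 1.45 ± 1.98 against 11.2 ± 18.8. Without periodontitis 4 the periodontitis mean of CCL5 was 2061 FPKM; for CCL2 the control mean was 2.81 without control 2 and the periodontitis mean 0.864 without periodontitis 5. Pattern recognition receptors and adaptors had 19 of 30 lower (adjusted p = 0.154), with LY96, the partner of TLR4 in sensing lipopolysaccharide, at 48.7 ± 11.4 against 80.9 ± 11.7 FPKM. Anti-inflammatory mediators had 11 of 20 lower (adjusted p = 0.666); IL1RN, the antagonist of the interleukin-1 receptor, had a log2 difference of -1.20 ± 0.38 and SOCS2, a cytokine signal suppressor, one of 1.04 ± 0.36 (SE). NF-kappaB components had 11 of 25 lower (adjusted p = 0.937), with NFKBIA at 70.7 ± 19.3 against 101 ± 22.4 FPKM. Interferon-stimulated genes had 24 of 30 lower (adjusted p = 0.0987); their score in control 2 was 6.97, far above the other controls. Without control 2 the median was 0.27 instead of -0.38. The list passed without control replicate 1, 3, 4 or 5 (adjusted p = 0.0109, 0.00660, 0.0254 and 0.00441) or periodontitis replicate 4 (0.00546), and with an estimated correlation, all libraries in, p = 0.626. It also passed with depth as a covariate (median -0.66, adjusted p = 6.92e-06), with the platelet score as a covariate (-0.88, adjusted p = 4.49e-07) and by limma voom (adjusted p = 0.0452).

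Lists for tissue breakdown, bone resorption and effector functions did not pass either. Metalloproteinases, cathepsins and inhibitors had 14 of 26 members lower (limma camera adjusted p = 0.540), with cathepsin Z (CTSZ) at 356 ± 82.0 against 619 ± 68.6 FPKM and SERPINA1, the inhibitor of neutrophil elastase, at 284 ± 88.6 against 499 ± 75.9. Osteoclast differentiation genes had 17 of 29 lower (adjusted p between 0.666 and 0.711), with the signalling adaptor TYROBP at 1428 ± 307 against 2250.1 ± 138 FPKM. NADPH oxidase and oxidant defence genes had 18 of 24 lower (adjusted p = 0.139); PRDX1, a peroxidase, and CYBA, an oxidase subunit, had log2 differences of -0.94 ± 0.27 and -0.67 ± 0.27 (SE). Migration genes had 19 of 27 lower (adjusted p = 0.120), with SELPLG, the ligand of P-selectin, at 96.5 ± 36.1 against 169.6 ± 6.20 FPKM. Fc receptors had 11 of 15 lower (adjusted p = 0.499), FCGR2C, which can share reads with FCGR2B, having a difference of 0.99 ± 0.53. Genes of Fc-receptor phagocytosis signalling had 15 of 28 lower (adjusted p = 0.962), with GSN, which severs actin filaments, at 0.91 ± 0.32.

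Among the remaining lists, apoptosis regulators had 17 of 34 members lower (limma camera adjusted p = 0.754), cholesterol and lipid handling 14 of 23 (adjusted p = 0.666), glycolysis and hypoxia 11 of 29 and circadian clock genes 3 of 10 (adjusted p = 0.540). Glucocorticoid-responsive genes had 6 of 14 lower (adjusted p = 0.711), immediate-early genes 15 of 24 (adjusted p = 0.143) and replication-dependent histone genes 9 of 17, the glycolysis and histone lists having adjusted p between 0.666 and 0.711, again by limma camera. TNFRSF1A, a receptor of tumor necrosis factor, averaged 50.2 ± 21.3 against 78.1 ± 10.8 FPKM, PLIN2, a coat protein of lipid droplets, 11.8 ± 4.27 against 18.3 ± 3.24, and PKM2, a glycolytic kinase, 1230.2 ± 644 against 629 ± 163. The clock gene ARNTL averaged 13.5 ± 5.11 against 8.80 ± 1.65 FPKM, the haptoglobin-haemoglobin receptor CD163 20.2 ± 19.7 against 30.7 ± 4.23, and the transcription factor KLF2 134 ± 26.8 against 204 ± 55.4; without periodontitis 1 the periodontitis mean of CD163 was 11.6. In the apoptosis and glucocorticoid lists the camera direction was down while the medians were 0.01 and 0.01; in the NF-kappaB list it was down with a median of 0.10, and in the Fc-receptor phagocytosis list the median was -0.03 and the mean was 0.00859. The mitochondrially encoded list had 0 members in the tables.

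Of 12107 genes tested, 0 passed limma's adjusted p of 0.05 in either direction, the smallest adjusted p being 0.328. At an unadjusted p of 0.05, 747 genes were on the higher side and 1029 on the lower side, 14.7% of those tested against 5% by chance. The groups did not overlap for 265 genes, 2.19% against 0.794% by chance. Both chance shares are expectations that do not allow for genes varying together. Of 100 splits of the libraries, the real one included, 8 gave as many genes at the unadjusted threshold. Chance could therefore not be excluded. Adjusted over the list alone, 1 member of any list passed: MARCKS, which links the membrane to the actin cytoskeleton, in the Fc-receptor phagocytosis list (limma adjusted p = 0.0173). That adjustment does not allow for the number of lists. Over all tested genes MARCKS had a limma adjusted p of 0.328. Limma voom on implied fragments also gave 0 genes, with 1637 at the unadjusted threshold. An exact permutation test per gene gave 0, with 1546 at that threshold. Its smallest possible p is 0.00794, which only a large number of genes together could carry past adjustment. That 0 was therefore nearly fixed by the size of the groups. Leaving out periodontitis 1 gave 5 genes by limma, and weighting libraries by their spread (limma arrayWeights) gave 935. The weights came from each library's distance to its own group mean, so libraries unlike their group counted less. No other split of the libraries was weighted, so the 935 cannot be set against chance.

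The 12 genes with the smallest unadjusted p on the higher side did not pass the adjusted threshold (limma adjusted p = 0.328 for each). RSPH9, a component of the radial spokes of motile cilia (chromosome 6, 43612767 to 43638748 in the deposited tables, whose genome build is not given in the sources used here), averaged 26.5 ± 15.5 against 2.96 ± 0.795 FPKM, a log2 difference of 2.46 ± 0.54 (SE). In periodontitis 1 RSPH9 stood at 3.16 FPKM, within the range of the controls. AFP, the fetal serum protein alpha-fetoprotein (chromosome 4, 74301933 to 74321492), averaged 5.85 ± 3.43 against 0.573 ± 0.990 FPKM, the control mean being 0.131 without control 1. SKI, a repressor of TGF-beta signalling, averaged 16.1 ± 3.82 against 8.53 ± 0.340, and ZYX, zyxin of focal adhesions, 513 ± 173 against 253 ± 25.8. The kinases CDC42BPB and DMPK had log2 differences of 0.86 ± 0.20 and 1.16 ± 0.28, and DMWD, which lies next to DMPK on chromosome 19, had 0.98 ± 0.25. The Polycomb gene PHC1 was at 1.11 ± 0.27, the mitochondrial transporter ABCB10 at 0.89 ± 0.22, COQ6 of coenzyme Q synthesis at 0.71 ± 0.19, and VPS8 of endosomal tethering at 0.78 ± 0.21. GOLGA8A, a golgin with near-identical copies that can share its reads, was at 1.46 ± 0.37.

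On the lower side, the 12 genes with the smallest unadjusted p likewise did not pass (limma adjusted p = 0.328 for each). MARCKS (chromosome 6, 114178527 to 114184652) averaged 21.4 ± 11.9 against 63.1 ± 19.7 FPKM, a log2 difference of -1.62 ± 0.35 (SE). FOLR2, a folate receptor of myeloid cells, averaged 7.37 ± 3.08 against 14.9 ± 1.91, and CECR1, which encodes adenosine deaminase 2, 116 ± 26.8 against 206 ± 13.4. The glutamine transporter SLC1A5 averaged 31.8 ± 4.40 against 50.9 ± 4.74 FPKM and the mitochondrial flavoprotein AIFM1 8.87 ± 1.56 against 14.6 ± 1.73. The transcription factor ATF5 was at -1.08 ± 0.25. TOMM34, a cytosolic partner of mitochondrial import, was at -0.90 ± 0.19 on the log2 scale, CRELD2 of the endoplasmic reticulum at -0.98 ± 0.22, EID2 at -0.91 ± 0.20, FAM207A at -1.08 ± 0.23 and CTNNBL1 at -0.80 ± 0.19. RASA4, a Ras GTPase activator with a near-identical copy, RASA4B, that can share its reads, was at -0.92 ± 0.20.

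**Figure D2:**
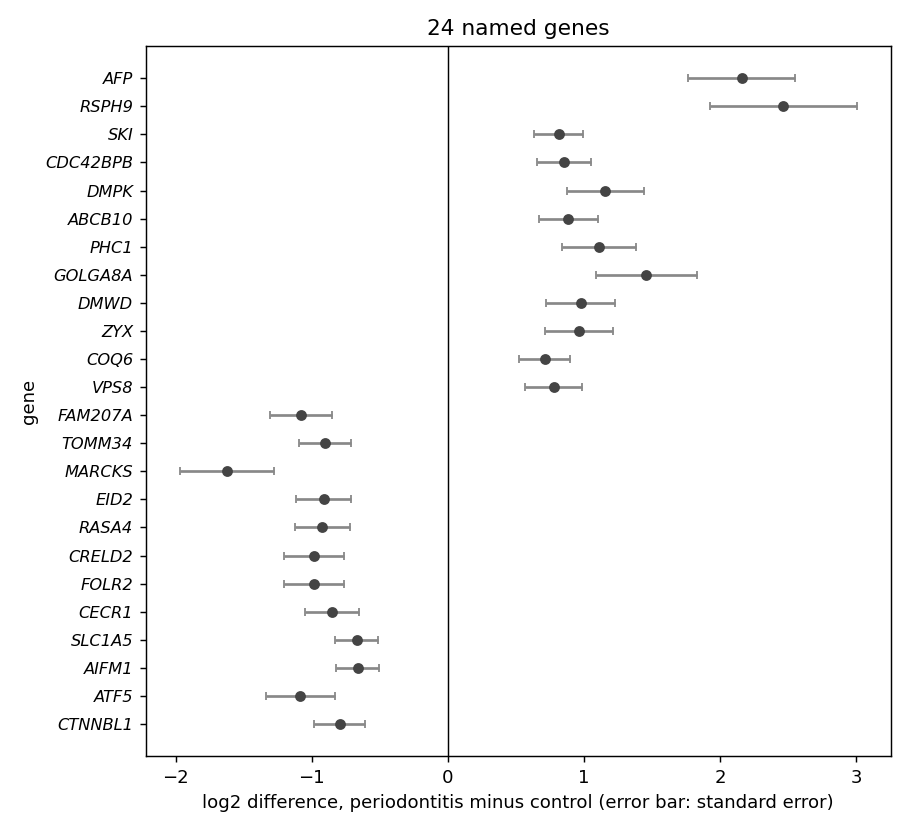
Log2 difference (periodontitis minus control, on the log2(scaled FPKM + 1) scale) of the genes named above, 12 per direction, with bars of 1 standard error from limma (n = 5 each). Differences run from -1.62 for MARCKS to 2.46 for RSPH9, and none passed the adjusted threshold.

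Over whole profiles, the libraries of a group were not closer to one another than to the other group by more than chance: the ratio of between-group to within-group squared distance was 1.17 (exact permutation p = 0.0873 over 126 splits, n = 5 each). Without periodontitis 1 the ratio was 1.47 (exact permutation p = 0.0159) and without periodontitis 5 it was 1.28 (exact permutation p = 0.0317). The first principal component held 36.1% of the variance and followed log2 depth over the 10 libraries (Pearson r = -0.95, permutation p = 3.00e-05, Spearman rho = -0.95, permutation p = 1.00e-04). Periodontitis 1 lay at -46.4 on it, beyond the controls, and control 2 at 8.82, among the periodontitis libraries. The labels of these 2 libraries were taken as given and were not checked here; every group value rests on them. The platelet score followed depth as well (Pearson r = -0.86, permutation p = 0.00143, Spearman rho = -0.89, permutation p = 0.00110), and so did the classical monocyte score (Pearson r = 0.93, permutation p = 1.80e-04, Spearman rho = 0.96, permutation p = 3.00e-05). Scores of ribosomal proteins, oxidative phosphorylation, MHC class II and heat shock genes rose with depth with Pearson r from 0.74 to 0.81 and Spearman rho from 0.72 to 0.88 (permutation p at most 0.0147 and 0.0237). Of these 8 relations, all had adjusted permutation p below the threshold except rho of the basophil and eosinophil list, which had r = -0.64 and rho = -0.31 (permutation p = 0.0430 and 0.388; adjusted 0.0430 and 0.388).

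Leaving out the 2 libraries with depths farthest from the median, periodontitis 3 and 4, the first component had r = -0.90 with depth, the platelet score -0.91 and the classical monocyte score 0.94. The ribosomal, oxidative phosphorylation, MHC class II and heat shock scores kept r of 0.76, 0.73, 0.67 and 0.63, and the basophil and eosinophil relation rested on those 2 libraries (r = 0.16 without them). Adjusted permutation p over the 8 relations was at most 0.0168 for r and 0.0271 for rho in the other relations. Inside the groups, with depth and score centred per group, the first component had r = -0.96 and rho = -0.80 with depth (two-sided exact permutation p = 8.33e-04 and 0.0192, adjusted over 8 relations 0.00667 and 0.0511; r = -0.88 without periodontitis 1 and 4). The platelet score had r = -0.82 and rho = -0.80 there (two-sided exact permutation p = 0.0135 and 0.0192, adjusted 0.0269 and 0.0511; r = -0.48 without the same 2). For the ribosomal score r was 0.72 and rho 0.40 (two-sided exact permutation p = 0.0562 and 0.311, adjusted 0.0788 and 0.415; r = 0.91 without them). The oxidative phosphorylation, MHC class II, heat shock, classical monocyte, and basophil and eosinophil scores had r of 0.73, 0.79, 0.66, 0.90 and -0.51 (two-sided exact permutation p = 0.0591, 0.00701, 0.104, 0.00576 and 0.365; adjusted 0.0788, 0.0187, 0.119, 0.0187 and 0.365). Their rho was 0.45, 0.65, 0.25, 0.85 and -0.15 (two-sided exact permutation p = 0.246, 0.0761, 0.544, 0.00931 and 0.735; adjusted 0.394, 0.152, 0.622, 0.0511 and 0.735), and without periodontitis 1 and 4 their r was 0.83, 0.72, 0.48, 0.93 and -0.34.

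As list scores per library, 0 of 31 lists passed the two-sided exact permutation test after adjustment (smallest adjusted p = 0.246), 5 having an unadjusted exact permutation p under 0.05. These were the ribosomal, oxidative phosphorylation, MHC class II, heat shock, and basophil and eosinophil lists, with score differences of -0.81 ± 0.36, -0.49 ± 0.18, -0.61 ± 0.18, -0.47 ± 0.16 and 0.87 ± 0.42 (SE). The platelet difference was 1.18 ± 0.63 (exact permutation p = 0.111, n = 5 each). The smallest p this test can give here is 0.00794, so 1 list alone could not pass adjustment over 31 lists.

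**Figure D3:**
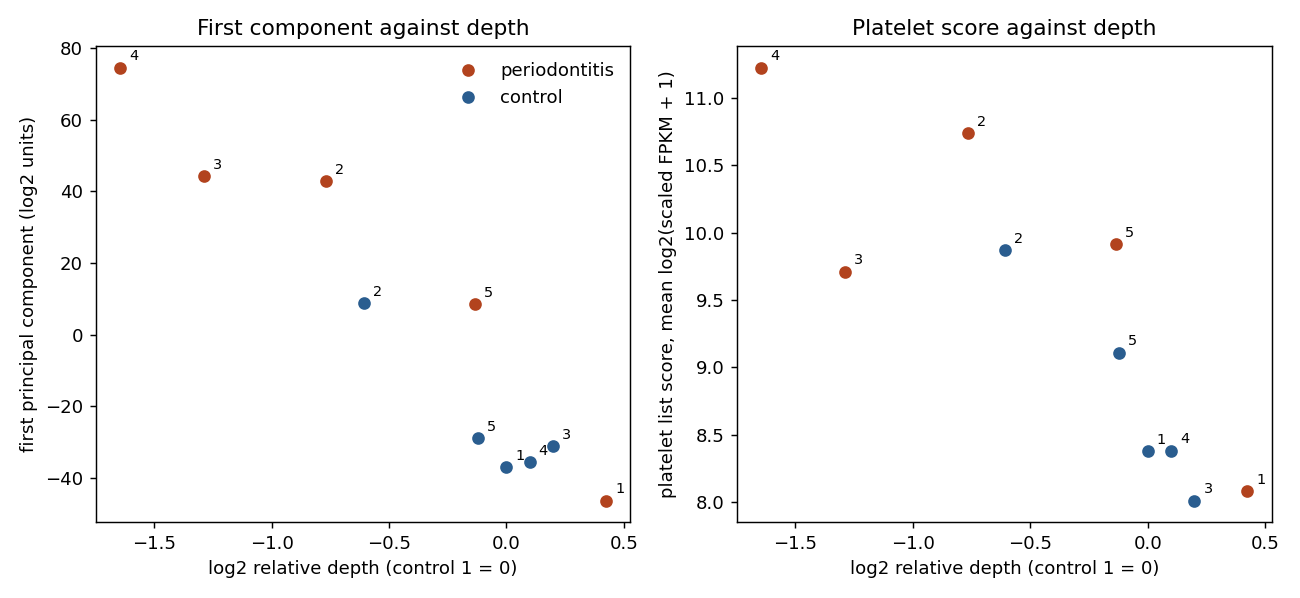
First principal component (left, log2 units) and platelet list score (right, mean log2(scaled FPKM + 1)) against log2 depth relative to control 1, each point being 1 library labelled with its replicate number. Both fall as depth rises (r = -0.95 and -0.86 over 10 libraries), with periodontitis 4 at the shallow end and periodontitis 1 at the deep end.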

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

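The test on other blood cell lists and the count of splits for genes past the adjusted threshold were set after their results had been seen; the other tests were written before, but with the list medians and the relation of the first component to depth already known. Values were picked out where the highest or lowest of a group's 5 libraries lay apart from the rest by more than Dixon's limit. Chance gives this in about 5% of groups, and 20 of 262 groups of values met it, 7 of them in control 2 and 8 in periodontitis 4.

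Control 2 had an interferon-stimulated gene score of 6.97 (nearest 4.25), with IFIT2 at 5.56 (nearest 3.50) and the chemokine CCL2 at 5.51 (nearest 2.33), all on the log2 scale. In the same library PLIN2 was low at 3.76 (nearest 4.34), the NK gene SH2D1B low at 1.19 (nearest 3.15) and DMWD high at 2.57 (nearest 2.08). It lay at 8.82 on the first principal component, the nearest control being at -28.8. Periodontitis 4, the shallowest library, had a basophil and eosinophil score of 4.38 (nearest 2.69), with TPSAB1 at 4.50 (nearest 1.49) and HDC at 2.88 (nearest 1.30), and HBB at 10.59 (nearest 5.20). Its NF-kappaB score was low at 3.71 (nearest 4.01), as were CLEC10A at 1.71 (nearest 4.08) and ENHO, listed at 0 (nearest 2.09), and SH2D1B was high at 4.69 (nearest 3.65). Periodontitis 1 had the highest MHC class II score of its group, 7.02 (nearest 6.20), and FCN1 at 10.73 (nearest 9.61), and the lowest RSPH9, 2.06 (nearest 4.59). Control 1 had AFP at 1.74 (nearest 0.28) and control 5 ARNTL at 2.80 (nearest 3.29).

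The ribosomal, oxidative phosphorylation and MHC class II lists had medians below zero in periodontitis, -0.67 on average. After every library was thinned to the shallowest depth the average was -0.68 (SE of the score difference 0.23). Thinning keeps the expected FPKM, so the medians of well-expressed genes could hardly move. It therefore does not decide on the number of sampled fragments. A property that goes with depth, such as RNA quality or input, was not argued against. The 3 medians were -0.44, -0.30 and -0.39 with depth as a covariate and -0.24, -0.22 and -0.09 without the 3 shallowest libraries. Transcript length and GC content were argued against, the average being -0.61 (SE 0.22) once each library's trends were removed. Dilution of monocyte RNA by platelet RNA cannot be told apart from a change within monocytes: with the platelet score as a covariate the group difference of the mean score was -0.39 (SE 0.24, 95% interval -0.95 to 0.17), an interval that holds both zero and the unadjusted -0.64. Disease itself and such a property both stay open.

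The platelet list stood above zero in periodontitis, with a median of 1.24. After thinning the median was 1.25 (SE of the score difference 0.63). As above, thinning could hardly move it and does not decide on the number of sampled fragments. With depth as a covariate the median was 0.49 and without the 3 shallowest libraries 0.31, so a property that goes with depth stays open. A general carry-over of blood cells stays open: 3 of 4 other lists were higher by more than 1 standard error (erythroid 0.70 ± 0.55, neutrophil 0.38 ± 0.34, B and plasma cell 0.43 ± 0.43) while the NK cell list was not (0.18 ± 0.41), although it passed limma camera with depth as a covariate (adjusted p = 0.0428; with an estimated correlation and no covariate p = 0.695). The dendritic cell list, which was not among the 4, was lower by more than 1 standard error (-0.34 ± 0.29). Platelets bound to monocytes and free platelets in the product may both contribute, and these data hold no value that separates them. More of either kind of platelet in disease was not tested.

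The first principal component followed depth. After thinning, the component still followed the original depth with an absolute r of 0.949 (permutation p = 2.00e-05). Its Spearman rho was -0.94 (permutation p = 1.60e-04), and its r was -0.90 without periodontitis 3 and 4. Thinning keeps the expected FPKM, so a component carried by well-expressed genes could hardly move. Thinning therefore does not decide on the number of sampled fragments here either. Depth may stand for another property of the library, such as the RNA that went into it, which was not tested. A score of 18 nuclear-retained or intron-holding transcripts rose with the component (r = 0.736, permutation p = 0.0102; Spearman rho = 0.82, permutation p = 0.00590; r = 0.77 without the same 2; 3 relations, adjusted permutation p at most 0.0102 for r and 0.00590 for rho). The platelet score rose with the component more closely (r = 0.935, permutation p = 1.60e-04). Its Spearman rho was 0.84 (permutation p = 0.00344), and its r was 0.96 without the same 2. Less cytoplasmic message in those libraries remains a hypothesis, since the nuclear-retained relation was found and tested on the same 10 libraries. It was not told apart from platelet content.

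Of 100 splits of the 10 libraries drawn from 126, the real one included, 8 gave as many genes at an unadjusted p of 0.05 as the real 1776, the highest of the others giving 4841, so chance could not be excluded. For lists passing limma camera, 57 of 100 splits gave as many as the real 7, up to 16, so chance could not be excluded there either. For genes past the adjusted threshold the real count of 0 is reached by all 100 splits, so the test is void. 9 of the other splits gave at least 1 gene. The highest of them gave 3017 genes; it exchanged periodontitis 1 with control 2 and thereby put the 4 shallowest libraries on one side. That split was picked as the highest, and what its genes follow was not tested. Its gap in mean log2 depth was -1.01, against -0.60 for the real grouping. Whether the labels of these 2 libraries are right was not checked here, and an exchange would change every group value.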

How the results depend on the processing

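The relation of scores to depth inside the groups, depth or platelet score as a covariate, leaving out the 3 shallowest libraries or the failed estimates, thinning, limma voom and removal of length and GC trends were chosen after seeing the data. The count of genes past limma's adjusted p stayed at 0 in all settings but 2: it ran from 0 to 5 when 1 library was left out, the 5 coming without periodontitis 1 (RSPH9 and SKI higher, FOLR2, FGL2 and the small RNA SNORA43 lower; FGL2 and SNORA43 were named after their values were seen), and it was 935 with limma arrayWeights (497 higher, 438 lower, 5 of the 5 among them). Those weights were set by each library's distance to its own group mean. They ran from 0.272 for periodontitis 1 to 3.78 for control 3, and control 2 had 0.486. No other split was weighted, and the cause of the 935 was not tested further. Genes at an unadjusted p of 0.05 were 1776, 624 with depth as a covariate, 1011 with the platelet score, 220 without the 3 shallowest libraries, which leaves 2 periodontitis libraries, and from 1072 (without control replicate 4) to 3831 (without periodontitis replicate 1) when 1 library was left out, with 1078, 1108 and 1161 without periodontitis replicate 2, control replicate 5 and control replicate 1. The 7 lists passing limma camera became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.830 and 0.231), and 6 to 9 when 1 library was left out. With FPKM as deposited, 4 of 9 passing lists were higher, against 2 of 7. Of the 7 lists, the classical monocyte median turned to 0.14 without the 3 shallowest libraries (adjusted p = 0.403; over all alternatives adjusted p ran up to 0.901), and no other turned its direction. With the platelet score as a covariate, which says nothing of the platelet list itself, the classical monocyte, MHC class II, and basophil and eosinophil lists no longer passed (adjusted p = 0.901, 0.0991 and 0.221). With depth as a covariate the classical monocyte (-0.14, adjusted p = 0.734) and the basophil and eosinophil lists (0.0692) did not. Histone genes passed as lower with depth or platelet score as a covariate and without the 3 shallowest libraries (adjusted p = 0.0365, 4.62e-04 and 0.00174), immediate-early genes without the 3 shallowest libraries and without control replicate 3 (0.0353 and 0.00563), and clock genes as higher with the platelet score as a covariate (0.0321). With an estimated correlation, all libraries in, p = 0.845, 0.477 and 0.633. The count of list scores past the exact permutation test stayed at 0 throughout. With 5 libraries per group that test cannot give p below 0.00794, so it had little room to pass. The separation ratio ran from 1.07 to 1.47 when 1 library was left out and was 0.954 without the 3 shallowest (exact permutation p = 0.619), the cause not being tested. Over 2625 values of 98 named genes and 865 of 31 lists, 3 and 93 changed sign without passing the threshold in either setting; a first labelling had counted these as reversals, and after they had been seen that word was kept for values past the threshold in at least 1 setting. DESeq2 was not run, since the tables hold no counts. No paired analysis was possible because the replicate numbers only follow the order of the records. Depth limits what the shallow libraries can show of genes near the filter.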

Other observations

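10 gene families, defined by symbol after the lists had been seen but before the families' own values were, were tested like the lists; their values with depth were added after that result had been seen. Members of the fixed lists were left out of them. Levels are given as mean ± SD with n = 5 each. Mitochondrial ribosomal proteins fell by a median of 0.47 on the log2 scale in periodontitis, 68 of 76 being lower (limma camera adjusted p = 4.90e-13; with an estimated correlation p = 0.0607), with MRPL47 at 15.8 ± 3.11 against 24.2 ± 2.14 FPKM. Proteasome subunits fell by a median of 0.43, 34 of 37 being lower (limma camera adjusted p = 1.75e-07; with an estimated correlation p = 0.103), with PSMC3 at 22.7 ± 6.79 against 41.6 ± 3.92. Translation initiation factors (41 of 55 lower, adjusted p = 2.30e-05; with an estimated correlation p = 0.124), chaperonin subunits (8 of 8 lower, adjusted p = 0.00159; with an estimated correlation p = 0.207) and vacuolar ATPase subunits (11 of 17 lower, adjusted p = 0.0288; with an estimated correlation p = 0.240) also passed limma camera; EIF5A averaged 92.6 ± 23.7 against 155 ± 18.7 FPKM and CCT4 23.7 ± 13.8 against 40.4 ± 4.85. Tubulins other than the platelet marker TUBB1 rose, 14 of 14 being higher (limma camera adjusted p = 5.75e-04; with an estimated correlation p = 0.159), with TUBB6 at 37.4 ± 25.4 against 11.7 ± 3.28 FPKM. TUBB1 was left out only as a member of a fixed list. The families were not tested with the platelet score as a covariate, so platelet content was not set aside. With an estimated correlation none of the 10 passed (p from 0.0607 to 0.811; smallest adjusted p = 0.344), and as scores none passed the exact permutation test after adjustment (smallest adjusted p = 0.0794). With log2 depth as a covariate the medians were -0.28 (mitochondrial ribosomal), -0.31 (proteasome), -0.15 (initiation factors), -0.17 (chaperonin), -0.22 (vacuolar ATPase) and 0.22 (tubulins), and limma camera still called them (largest adjusted p = 0.0335). Without the 3 shallowest libraries they were -0.16, -0.15, -0.07, -0.12, -0.09 and 0.11, and only the mitochondrial ribosomal and proteasome families passed (limma camera adjusted p = 1.05e-05 and 0.00177; 0.0530, 0.358, 0.0530 and 0.467 for the others).

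Over the 10 libraries the mitochondrial ribosomal, proteasome, initiation factor, chaperonin and tubulin scores had Pearson r with log2 depth of 0.88, 0.78, 0.85, 0.82 and -0.78 (permutation p = 0.00161, 0.00900, 0.00229, 0.00367 and 0.0111; adjusted over 10 relations 0.00537, 0.0150, 0.00572, 0.00734 and 0.0158). Spearman rho was 0.73, 0.79, 0.79, 0.88 and -0.85 (permutation p = 0.0205, 0.00912, 0.00906, 0.00163 and 0.00272; adjusted 0.0293, 0.0152, 0.0152, 0.00543 and 0.00680), and r without periodontitis 3 and 4 was 0.75, 0.66, 0.82, 0.88 and -0.87. The vacuolar ATPase score had r = 0.51 and rho = 0.35 (permutation p = 0.137 and 0.333, adjusted 0.152 and 0.333; r = 0.14 without the same 2). For the mediator, SR splicing factor, RAB and ZNF scores r was 0.95, -0.92, -0.52 and -0.12 (permutation p = 5.00e-05, 1.80e-04, 0.123 and 0.725; adjusted 5.00e-04, 9.00e-04, 0.152 and 0.725). Their rho was 0.98, -0.95, -0.50 and 0.39 (permutation p = 2.00e-05, 1.60e-04, 0.143 and 0.265; adjusted 2.00e-04, 8.00e-04, 0.179 and 0.295), and without those 2 libraries r was 0.89, -0.79, -0.83 and 0.37. Mediator subunits (21 of 28 lower, limma camera adjusted p = 0.0571), ZNF genes (158 of 350, adjusted p = 0.482), RAB GTPases (19 of 46, adjusted p = 0.669) and SR splicing factors (4 of 11, adjusted p = 0.689) did not pass.

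10 abundant liver transcripts summed to 8.67 ± 5.73 FPKM in periodontitis and 3.39 ± 2.44 in controls, beside AFP at 5.85 ± 3.43 against 0.573 ± 0.990 (two-sided exact permutation p = 0.0397 and 0.00794). ALB, the most abundant message of liver, averaged 0.0778 ± 0.117 against 0.0127 ± 0.0284 (SD, n = 5 each). A prediction for liver RNA was written and then dropped before the values were computed. It held that these transcripts would be higher in periodontitis with a sum above AFP, and the sum lies on that side. As the most abundant message of liver, however, ALB would exceed AFP in liver RNA. In periodontitis ALB lay far below AFP (0.0778 ± 0.117 against 5.85 ± 3.43 FPKM), which argues against liver RNA as the source of AFP. The mean distance between libraries was 0.957 log2 units per gene within periodontitis and 0.739 within controls (two-sided exact permutation p = 0.175). The 18 nuclear-retained transcripts had a score of 6.24 ± 0.36 in periodontitis and 5.93 ± 0.18 in controls (two-sided exact permutation p = 0.119, SD, n = 5 each).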
